A study of Homo sapiens with 3 samples.

How the data were processed

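RNA was measured in 3 libraries of the RCC4 renal carcinoma line treated with IFN-gamma and TNF, which the labels describe as biological replicates of 1 group. The labels' protocols record poly(A) selection, a directional library kit and sequencing on an Illumina instrument. Per the submitters' processing notes, FastQC, cutadapt 1.18, HISAT2 2.1.0 and featureCounts 2.0.0 were used with the genome build hg38. The annotation release, the strand setting and the counting options are not given in the sources used here.

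The deposited values are a signal per gene: gene counts that the authors divided by a size factor for each library, as read from the values themselves. In each library 100% of the nonzero values were whole multiples of what 1 read is worth, within 0.01 of a read. The recovered size factors were 0.946, 0.971 and 1.24, and the recovered totals were 29199806, 26264283 and 33458691 reads. Median-of-ratios factors from these 3 libraries alone would be 0.919, 0.932 and 1.18, so the source of the authors' scaling stays open. The planned design assumed counts, and the recovered whole reads took their place. Counts of 2 were far more common than counts of 1 (1621 against 269 genes in replicate 1), as when both mates of a read pair are counted. Reads are therefore not independent molecules, and every floor from a count of 0 covers counting error only.

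The 60605 gene identifiers were matched to GENCODE 29 (GRCh38): 58337 (96.3%) matched and held 99.9% of the reads. Exon lengths, gene spans and transcript GC content came from that annotation, whose release need not be the authors'. For each gene the share of its exon length inside other genes' spans on either strand was computed, and genes at 80% or more are called covered.

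Reads were scaled with TMM in edgeR 4.0.16 (R 4.3.3), and levels are RPKM over the union of exons, on the log2 scale with a pseudocount of 0.1. A gene counted as detected at a CPM of at least 1 in all libraries. The 19 gene lists, 21 gene pairs, tests and rule for named genes were fixed before the data were examined. The median level of each list was compared with 10000 random lists of the same size drawn from 19861 protein-coding genes, with a two-sided empirical p whose smallest value is 0.0002 and Benjamini-Hochberg adjustment over the lists. This describes these libraries, since genes are not replicates. List spread and list deviation per library were compared with 10000 lists matched on expression in 20 bins, for lists with at least 3 detected members. The 2 list contrasts used 100000 permutations of list labels over genes. A gene pair was measured where both genes had at least 10 reads in some library and a read in each, and its log2 ratio was called past the replicate spread when all libraries had the same sign and the mean exceeded 2 SD. With 1 group there was no test between groups and no count of changed genes. Replicate spread was summarised as the common biological coefficient of variation of edgeR with an intercept only.

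The rule named the 15 with the highest mean CPM, up to 4 highest and 3 lowest members of each list, both genes of each pair, and the 10 with the largest coefficient of variation among genes with a mean CPM of at least 5. Where several members of a list were tied at 0, those named were taken from the tie. Some genes that the rule names, and the ratios that hold them, are not reported here, though they count in the totals. Other named genes, among them IRF9, MX1, IFITM2, the IFIT and OAS genes, CIITA and the ribosomal protein genes, were chosen after their values were seen.

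The methods were tested on simulated data built from the real means and library sizes. A biological coefficient of variation of 0.2 was recovered as 0.198 over 11266 genes. List deviation was tested on 10 lists of 20 genes raised in replicate 1 beside 10 unchanged lists. At a simulated coefficient of variation of 0.28, near that of all 3 libraries, 2, 9 and 10 of 10 lists were found at 1.2, 1.5 and 2-fold, with 0, 1 and 0 false calls, and the test of list spread found 0, 3 and 10. At 0.07, near that of replicates 2 and 3, deviation found 10 of 10 at each fold, with 1, 1 and 0 false calls. Each simulated library had the same independent spread, whereas the real spread was far smaller without replicate 1 and followed GC content. The numbers of lists found need not hold for the real libraries. For list level, 1, 5, 7 and 10 of 10 lists raised 2, 4, 16 and 256-fold were found with 0 false calls, numbers that vary with the genes drawn. The 256-fold size and the coefficient of variation of 0.28 were added after earlier runs, the former because smaller shifts were missed. The level test thus resolves only large differences. A planted GC trend was recovered at a Spearman rho of 0.982 and fell to 0.0195 after GC correction.

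Reads shared by near-identical genes cannot be assigned with certainty, which bears on the HLA, GBP and IFITM families, C4A and C4B, HSPA1A and HSPA1B, SAA1 and SAA2, the keratins, and ACTB and ACTG1. The same holds for overlapping and antisense genes, since the strand setting of the counting is not stated.

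Alternatives fixed at the same time were DESeq2 1.42.0 size factors, total counts, leaving out each replicate, other detection limits, no length scaling, a background of detected genes, a pseudocount of 1, members with at least 5 CPM, and no filter on low counts. Those chosen after seeing the data were leaving out covered genes, the exon length outside other genes' spans, GC correction by the median of 20 bins, and the authors' deposited scaling. Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.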

Results

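Poly(A) RNA was sequenced from RCC4, a human clear cell renal carcinoma line that lacks a functional VHL protein and here carried a Cas9 vector. All 3 libraries came from cells exposed for 24 h to IFN-gamma at 1000 U/mL together with TNF at 25 ng/mL. Each was a biological replicate grown in 3 flasks. Untreated cells were not analysed here, so the values below are levels in treated cells and ratios within a library, not responses to the cytokines. The libraries held 29199806, 26264283 and 33458691 reads assigned to genes in replicates 1, 2 and 3. At a level of at least 1 CPM (TMM-scaled) in every library, 11266 genes were detected, 10201 of them protein-coding. Levels of single genes are given as RPKM, the CPM per kilobase of exon, as mean ± SD over 3 libraries. The counting options are not given, so these values may include reads from outside exons.

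The most abundant transcripts were those of the cytoskeleton, translation, glycolysis and the mitochondrial genome. MT-RNR2, the mitochondrial large ribosomal RNA, led in the mean over libraries at 14440 ± 1466 CPM (SD, n = 3). Next came FLNA, which crosslinks actin filaments, at 13560 ± 3476 CPM, and ACTB at 10290 ± 3862 CPM. In replicate 1 FLNA and ACTB exceeded MT-RNR2, at 17520 and 14710 against 12820 CPM. EEF1A1, MYH9, ACTG1, EEF2, PKM and ENO1 were also among the 15 highest, as were the mitochondrial MT-CO1, MT-ND4 and MT-CO2. TGFBI, a secreted matrix protein, stood at 3987 ± 182 CPM. A pair of genes annotated as long noncoding RNAs on chromosome 21 completed the 15. CH507-528H12.1 (GRCh38, 8380665 to 8410645) stood at 5509 ± 2577 CPM and CH507-513H4.1 (8197620 to 8227646) at 4728 ± 527 CPM. They have the same exon length and GC content, so the split of reads between them is uncertain. The RNA that gave their reads was not examined. Mitochondrially encoded genes took 5.22% ± 0.072 of the reads. The 98 protein-coding genes whose symbols start with RPL or RPS and a digit took 3.73% ± 0.311. This set leaves out RPLP0 and is wider than the ribosomal protein genes compared by overlap below. Some of its members, such as RPL15, were listed at 0 reads. Replication-dependent histone genes, 83 chosen by the start of their symbols, took 0.0893% ± 0.0036.

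Replicates 2 and 3 resembled each other far more closely than either resembled replicate 1. Between replicates 2 and 3, 0.142% of the 11266 detected genes differed by more than 2-fold, against 12.1% between replicates 1 and 2 and 14.7% between replicates 1 and 3. The 10 most variable genes with a mean of at least 5 CPM were ZNF117, VPS13A, SAMD9, CCDC82, ASPM, RP5-972B16.2, ZNF92, SAMD9L, ZNF518A and TPR. All 10, and all of the 100 most variable, were lowest in replicate 1. SAMD9L, an interferon-inducible antiviral gene, had 182, 2707 and 4470 reads in replicates 1, 2 and 3. ASPM, a mitotic spindle gene, had 110, 2105 and 3528 reads. Pearson's r across genes on the log2 scale was 0.995 for replicates 2 and 3, 0.955 for replicates 1 and 2 and 0.942 for replicates 1 and 3. Genes are not independent replicates. The common biological coefficient of variation from edgeR was 0.281 over 3 libraries and 0.0731 without replicate 1. As a check only for a library deposited more than once, the chi-square per degree of freedom was 93.2, 136 and 12.9 for pairs 1 and 2, 1 and 3, and 2 and 3, values that counting both mates of a pair inflates.

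The difference between replicate 1 and the other 2 libraries followed the GC content of the transcripts. In the lowest of 20 GC bins, with a median GC content of 37.4%, the median log2 ratio of replicate 1 to the mean of replicates 2 and 3 was -1.67, and in the highest bin, at 65.0%, it was 0.43. Replicate 3 over replicate 2 ran from 0.22 to -0.07 over the same bins. Of 9095 protein-coding genes with a mean of at least 5 CPM, 1245 were below 50% of the other libraries' mean in replicate 1, and 4 were more than 2-fold above it.

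**Figure D1:**
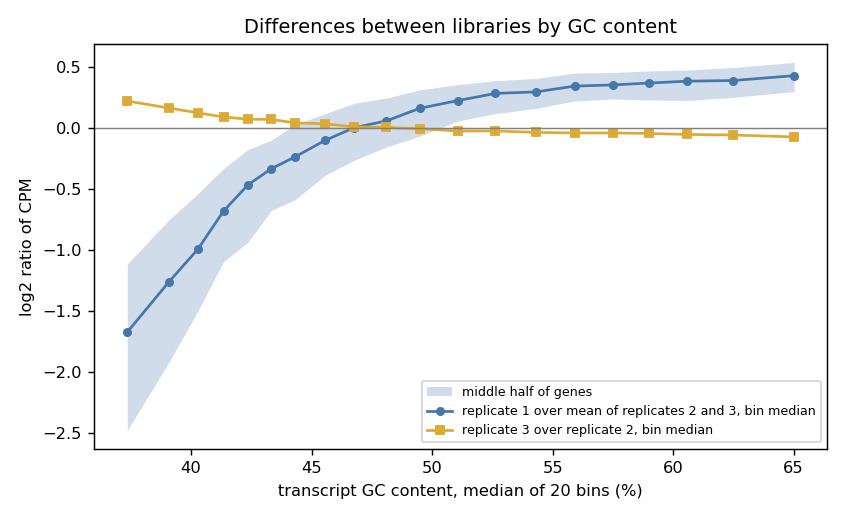
Median log2 ratio of CPM between libraries (vertical axis) in 20 bins of transcript GC content (horizontal axis, percent), for 9095 protein-coding genes. Circles show replicate 1 over the mean of replicates 2 and 3 with the middle 50% of genes shaded, squares show replicate 3 over replicate 2; the circles run from -1.67 to 0.43.

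Many protein-coding genes were listed at 0 reads where their exons lay inside the span of another gene. Of 2150 protein-coding genes whose exons were wholly inside other genes' spans, 41 (1.91%) were detected, against 4967 of 9483 genes (52.4%) with no such overlap. The genes at 0 included RPL15, RPL32, RPL35A and RPS4X, ribosomal proteins that every cell needs. TAP1, the peptide transporter subunit on chromosome 6 (GRCh38, 32845209 to 32853978, minus strand), lies within the span of PSMB9 (32844136 to 32859585, plus strand) and had 0 reads in each library. Of the 362 genes in the 19 fixed lists, 43 had at least 80% of their exon length inside other spans, and 5 of these 43 were detected. For these 43, called covered genes below, a 0 is given only as listed. SDHA, an enzyme of the respiratory chain, was also listed at 0 reads in each library without any such overlap. Zeros of other genes with little or no overlap are therefore also given only as listed. Levels were not corrected for partial overlap unless stated. Such overlap took in 46.0% of the exons of DNAJB1, 43.0% of BCL2L1, 41.5% of VIM and 39.0% of SOD2.

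**Figure D2:**
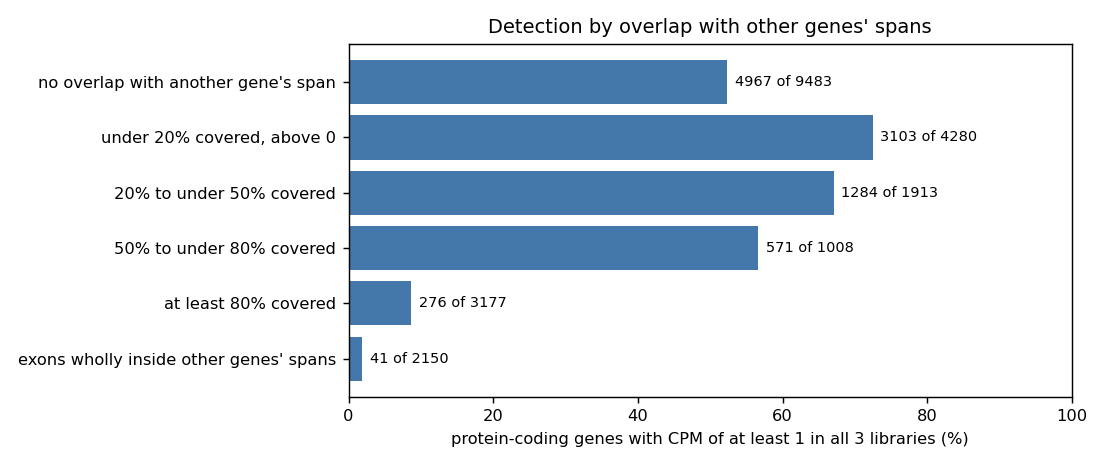
Percent of protein-coding genes with at least 1 CPM in all 3 libraries (horizontal axis) by the share of their exon length inside other genes' spans in GENCODE 29, with the number detected beside each bar. The class of at least 80% contains the genes wholly inside; detection was 52.4% without overlap and 1.91% for genes wholly inside.

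Over the 19 lists, 234 of 362 genes were detected. The median level of 9 lists lay above that of random lists of protein-coding genes, and no list lay below. Those 9 were IFN-gamma signalling, interferon-stimulated effectors, MHC class I presentation, the TNF and NF-kappa-B pathway, cell death machinery, HIF targets and regulators, proliferation, the unfolded protein and stress response, and the housekeeping reference. With covered genes left out of lists and background, 9 lists lay above and 2 below.

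**Figure D3:**
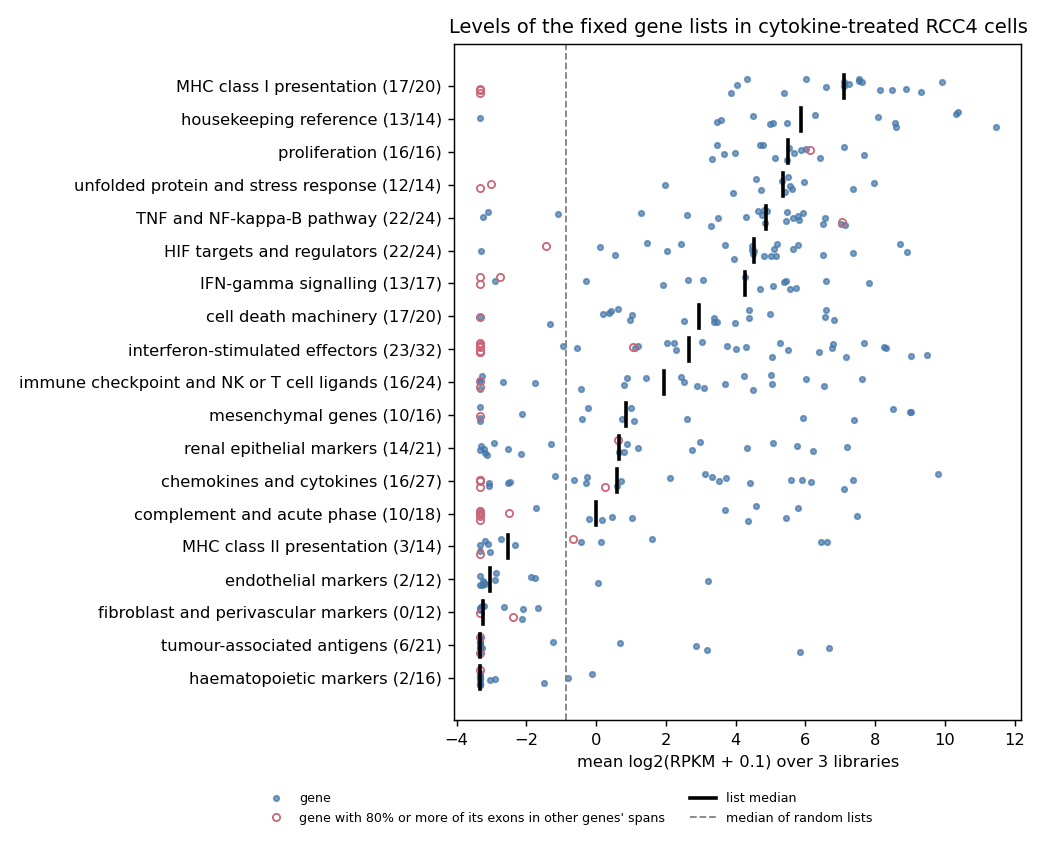
Mean log2(RPKM + 0.1) over 3 libraries (horizontal axis) of each gene in the 19 fixed lists, with the number of members detected and listed in parentheses. Filled points are genes, open points are genes with at least 80% of their exons in other genes' spans, thick bars are list medians and the dashed line is the median of random lists; MHC class I presentation had the highest median.

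The IFN-gamma signalling list had 13 of 17 members detected and a median of 19.1 RPKM against 0.475 for random lists (adjusted p = 0.00054). The feedback inhibitor SOCS3 stood at 97.6 ± 17.2 RPKM (SD, n = 3), the kinase JAK1 at 52.7 ± 2.79 RPKM and STAT2 at 47.1 ± 4.95 RPKM. STAT3 stood at 42.4 ± 7.18 RPKM. The receptor chains IFNGR1 and IFNGR2 stood at 6.40 ± 2.24 and 8.27 ± 0.98 RPKM, and their ratio did not exceed the replicate spread (log2 -0.43 ± 0.71). IFNGR2 has 47.4% of its exons inside other spans, and with the exon length outside them the ratio was -1.36; with GC correction it was -0.37 and passed the replicate spread. IRF8, a factor of blood cell lineages, had 4, 8 and 4 reads in replicates 1, 2 and 3. IRF1 and SOCS1 were listed at 0 reads in each library and IRF9 at 2, 6 and 9; all 3 are covered genes.

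Interferon-stimulated effectors reached 23 of 32 members detected, with a median of 6.22 RPKM against 0.448 for random lists (adjusted p = 0.0062). GBP1, a guanylate-binding GTPase of cell-intrinsic defence, was the highest at 717 ± 94.2 RPKM. BST2, which tethers budding virions, followed at 528 ± 62.2 RPKM, then the ubiquitin-like modifier ISG15 at 318 ± 48.5 RPKM and APOL1 at 306 ± 41.5 RPKM. Not all were high as measured: MX1 stood at 0.591 ± 0.0585 RPKM and IFITM2 at 0.461 ± 0.252 RPKM. The span of IFITM2 overlaps exons of IFITM1, and loss of reads to overlap was not excluded for MX1 or IFITM2. IFIT1, IFIT2, IFIT3, OAS2, OAS3, IFITM1, IFITM3 and IDO1 were listed at 0 reads in each library, and all 8 are covered genes. Of the 9 covered members 1 was detected. Without the 9 covered members, 22 of 23 were detected and the median was 32.7 RPKM, against 1.35 for random lists (adjusted p = 0.00047).

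The measured levels of antigen presentation genes differed by class. MHC class I presentation had the highest median of all 19 lists, 137 RPKM against 0.426 for random lists (adjusted p = 0.00054), with 17 of 20 members detected. MHC class II presentation had a median of 0.074 RPKM with 3 of 14 members detected and did not pass the test against random lists (adjusted p = 0.48). Its count was 7 at 0.1 CPM and 6 at 10 reads, and against detected genes its 3 detected members lay above random lists by 3.86 on the log2 scale (adjusted p = 0.017). The class I median exceeded the class II median by 9.62 on the log2 scale (SD over libraries 0.144; two-sided permutation of list labels over genes, p = 0.001, adjusted p = 0.002).

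Among class I genes, the chaperone CALR stood at 965 ± 151 RPKM, HLA-C at 636 ± 81.3 and HLA-B at 470.5 ± 33.5 RPKM. Of the immunoproteasome subunits, PSMB8 exceeded its constitutive counterpart PSMB5 1.90-fold (log2 0.93 ± 0.03) and PSMB9 exceeded PSMB6 1.49-fold (log2 0.57 ± 0.04). PSMB10 was below PSMB7 (log2 -1.55 ± 0.13). TAP1, TAP2 and ERAP2, all covered genes, were listed at 0 reads in each library, so the TAP1/TAP2 and ERAP1/ERAP2 ratios were not formed. HLA-C and PSMB10 have 76.9% and 46.8% of their exons inside other spans, and reads shared between the HLA genes make their split uncertain. With the exon length outside other spans, the log2 ratio was -0.64 for PSMB10/PSMB7; without length scaling it was 1.69 for PSMB8/PSMB5 and 1.66 for PSMB9/PSMB6.

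In the class II list, the invariant chain CD74 stood at 98.0 ± 8.99 RPKM and the protease CTSS at 87.5 ± 3.42 RPKM. The chains that present peptide were near 0. HLA-DRA, the invariant alpha chain of HLA-DR, had 22, 16 and 40 reads, HLA-DRB1 had 53, 35 and 25, and both lie outside other genes' spans. HLA-DOB was detected at 2.97 ± 0.364 RPKM, while HLA-DPB1 and HLA-DOA were listed at 0 reads in each library. HLA-DOB and HLA-DPB1 have 71.95% and 21.7% of their exons inside other spans. CIITA, the transactivator of class II genes, had 412, 421 and 475 reads, or 0.712 RPKM. IFI30, a covered gene, was listed at 0.

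The TNF and NF-kappa-B pathway was almost completely expressed, with 22 of 24 members detected and a median of 29.1 RPKM against 0.445 for random lists (adjusted p = 0.00054). SOD2, the mitochondrial superoxide dismutase, stood at 141 ± 13.2 RPKM, the adhesion molecule ICAM1 at 132 ± 13.8, TNIP1 at 130.5 ± 20.9 and TRAF1 at 98.0 ± 31.8 RPKM. The TNF receptor TNFRSF1A was at 55.3 ± 10.4 RPKM, whereas TNFRSF1B had 0, 0 and 2 reads. The adhesion molecule VCAM1 had 2, 2 and 6 reads. NFKB2 exceeded NFKB1 2.88-fold (log2 1.53 ± 0.09), and BIRC3 was below BIRC2 (log2 -1.61 ± 0.08). Both inhibitor-of-apoptosis genes were far lower in replicate 1, with 662, 3101 and 4793 reads for BIRC3 and 1279, 5770 and 8316 for BIRC2. Without length scaling the log2 ratio of BIRC3 to BIRC2 was -0.88, and ICAM1 has 81.5% of its exons inside other spans.

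The difference between the IFN-gamma signalling and TNF lists did not pass the test over genes. The medians of levels averaged over libraries differed by -0.61 on the log2 scale, with a two-sided permutation p of 0.35. With medians taken within each library, the sign was the same in all libraries, at -0.95, -0.73 and -0.71 in replicates 1, 2 and 3 (SD 0.135). These are a different statistic from -0.61, which lies outside their range, so the SD is not its error. Without covered genes the difference was 0.035 in the opposite direction, with an adjusted permutation p of 0.95.

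Chemokines and cytokines ranged from among the highest to 0, with 16 of 27 members detected (10 at 10 CPM). IL32, a proinflammatory cytokine, stood at 910.2 ± 209 RPKM, CSF1 at 164 ± 7.81, the monocyte attractant CCL2 at 139 ± 18.7 and CX3CL1 at 71.0 ± 7.66 RPKM. CXCL9 had 65, 105 and 99 reads, and CXCL10, CXCL11, CCL5 and IL18 were listed at 0 reads in each library; all 5 are covered genes. The list median, 1.40 RPKM, did not pass the test against random lists (adjusted p = 0.48). With the exon length outside other spans it lay above them (adjusted p = 0.021).

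Ligands that engage T and NK cells were expressed unevenly, with 16 of 24 members detected (10 at 10 CPM) and a median of 3.74 RPKM that did not pass the test against random lists (adjusted p = 0.087). CD70 stood at 199 ± 42.4 RPKM, CD40 at 92.1 ± 6.22, the death ligand TNFSF10 at 66.6 ± 20.8 and TNFSF9 at 32.7 ± 4.30 RPKM. CD274, which encodes PD-L1, stood at 8.79 ± 2.73 RPKM with 630, 1176 and 1457 reads. PDCD1LG2 and HHLA2 were listed at 0 reads in each library, as were the covered genes PVR and VSIR. As for SDHA, a 0 outside other spans need not mean absence.

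Cell death machinery was detected for 17 of 20 members, with a median of 7.58 RPKM (adjusted p = 0.013). The survival factors BCL2L1 and MCL1 stood at 112 ± 15.5 and 97.0 ± 11.4 RPKM, the pore-former BAX at 95.1 ± 15.9 and the necroptosis effector MLKL at 31.8 ± 0.325 RPKM. RIPK3, the kinase that acts on MLKL, was listed at 0 reads in each library with 28.9% of its exons inside other spans, as was the covered gene BAK1. The inflammasome sensor AIM2 had 10, 16 and 34 reads. Against detected genes only, the list no longer stood above random lists (adjusted p = 0.26).

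Complement and acute phase genes were detected for 10 of 18 members, with a median of 0.89 RPKM (adjusted p = 0.70). C3, the central complement component, was highest at 178 ± 3.46 RPKM. The C1 proteases C1S and C1R stood at 55.4 ± 4.02 and 43.7 ± 5.31 RPKM and their inhibitor SERPING1 at 24.1 ± 1.74 RPKM. C1R has 39.3% of its exons inside other spans against 3.54% for C1S, so the order of these proteases is uncertain. SAA2, PTX3 and HP were listed at 0 reads in each library, and these 3 are among the 6 covered members.

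The list of HIF targets and regulators, which holds hypoxia-inducible factors, their regulators and genes they drive, was detected for 22 of 24 members with a median of 22.7 RPKM against 0.478 for random lists (adjusted p = 0.00054). The glycolytic genes LDHA and PGK1 stood at 477 ± 36.6 and 425 ± 89.0 RPKM, the glucose transporter SLC2A1 at 164 ± 19.6 and IGFBP3 at 91.8 ± 14.5 RPKM. The carbonic anhydrase CA9 stood at 50.5 ± 13.5 RPKM and CA12 at 0.985 ± 0.14, a log2 ratio CA12/CA9 of -5.66 ± 0.53. EPAS1, encoding HIF-2-alpha, exceeded HIF1A by 6.38 ± 0.82 on the log2 scale, where HIF1A had 20, 48 and 67 reads. EGLN1, outside other genes' spans, had 1, 0 and 0 reads, and its level is left open as for SDHA. HIF1A has 92.2% of its exons inside other spans, and with the exon length outside them the EPAS1/HIF1A ratio was 2.70. CA9 has 38.5% of its exons inside other spans. The CA12/CA9 ratio was -6.36 with the exon length outside them and -3.53 without length scaling.

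Epithelial and mesenchymal genes were both present. Of the renal epithelial markers, 14 of 21 were detected (9 at 10 CPM), led by the keratins KRT8 at 147 ± 31, KRT18 at 74.8 ± 16.8 and KRT19 at 54.1 ± 9.04 RPKM. Of the mesenchymal genes 10 of 16 were detected, among them VIM at 528 ± 83.8, TGFBI at 510.5 ± 23.3 and FN1 at 168 ± 18.3 RPKM. The cadherin CDH2 stood at 61.3 ± 1.80 RPKM, while CDH1, the epithelial cadherin, had 32, 6 and 7 reads (log2 CDH2/CDH1 9.98 ± 1.44). The proximal tubule genes AQP1 and LRP2 had 0, 2 and 0 reads each, and GGT1, COL1A2 and MMP2 were listed at 0 reads in each library, as was the covered gene ITGA5. The list medians of 1.47 and 1.71 RPKM did not pass the test against random lists (adjusted p = 0.48 for both). PAX8 was below PAX2 (log2 -2.42 ± 0.11), but 95.7% of its exons lie inside other spans, and with the exon length outside them the ratio turned to 2.13.

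Proliferation genes were detected in full, 16 of 16, with a median of 44.9 RPKM (adjusted p = 0.00054). The replication clamp PCNA stood at 206 ± 8.37 RPKM, CDC20 at 139 ± 16.5, CCNB1 at 85.2 ± 1.09 and RRM2, a covered gene, at 70.9 ± 11.4 RPKM. The lowest were CDK1 at 13.7 ± 8.95, TYMS at 12.6 ± 1.92 and CCNE1 at 10.1 ± 2.20 RPKM. TYMS has 56.2% of its exons inside other spans. CDK1 was far lower in replicate 1, with 394, 1759 and 2864 reads.

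The unfolded protein and stress response was detected for 12 of 14 members with a median of 41.2 RPKM (adjusted p = 0.00054). The endoplasmic reticulum chaperone HSPA5 stood at 248.5 ± 15.5 RPKM and ATF4 at 165 ± 13.3, with DNAJB1 at 62.9 ± 11.8 and NQO1 at 49.1 ± 6.5 RPKM. CHAC1 stood at 3.83 ± 0.605 RPKM. The covered genes DDIT3 and ASNS were listed at 1, 0 and 2 and at 0 reads in each library. The housekeeping reference was detected for 13 of 14 members with a median of 58.5 RPKM (adjusted p = 0.00054). ACTB stood at 2923 ± 1098 RPKM, EEF1A1 at 1340 ± 159, GAPDH at 1274 ± 229 and RPLP0 at 388 ± 69.8 RPKM.

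Markers of other cell types were scarce. Of the haematopoietic markers 2 of 16 were detected, CSF1R at 0.82 ± 0.0818 RPKM and ITGAM at 0.256 ± 0.0458 RPKM. HBB and HBA1 were listed at 0 reads in each library, where 3 reads would be 0.110, 0.110 and 0.0862 CPM in replicates 1, 2 and 3. That limit covers counting error only, is too low where both mates of a pair were counted, and does not cover zeros such as that of SDHA. Of the endothelial markers 2 of 12 were detected, EGFL7 at 9.27 ± 2.01 and ESAM at 0.944 ± 0.104 RPKM, while KDR and EMCN were listed at 0 reads. The endothelial count was 6 at 0.1 CPM, 4 at 10 reads and 1 at 10 CPM, and the haematopoietic count was 0 at 10 CPM. Of the 12 fibroblast and perivascular markers 0 were detected at 1 CPM in all libraries, 1 without replicate 2 or without replicate 3, 2 at 10 reads and 5 at 0.1 CPM. PDGFRB had 32, 14 and 44 reads, and LUM and COL3A1 were listed at 0. The medians of the haematopoietic, endothelial and fibroblast lists did not pass the test against random lists (adjusted p = 0.064, 0.36 and 0.18). Without covered genes the haematopoietic list lay below random lists (adjusted p = 0.016).

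Of the tumour-associated antigens 6 of 21 were detected. MET, a growth factor receptor, stood at 102 ± 17.2 RPKM, the mitotic survivin gene BIRC5 at 57.1 ± 7.44, MUC1 at 9.17 ± 2.03 and PRAME at 7.27 ± 0.98 RPKM. GAGE1, PAGE4 and WT1 were listed at 0 reads in each library. The list median was 0 RPKM and did not pass the test (adjusted p = 0.064). Without covered genes it lay below random lists (adjusted p = 0.0084).

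Of the 21 fixed gene pairs 14 gave a ratio, and 13 of these 14 kept the same sign in all libraries with a mean above 2 SD. IFNGR1/IFNGR2 did not, except with GC correction. With 3 libraries the exact two-sided sign-flip permutation test cannot go below p = 0.25, which was its value for each of the 13 pairs. Without replicate 1 the count was 12, since CDH1 then had fewer than 10 reads in both libraries.

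**Figure D4:**
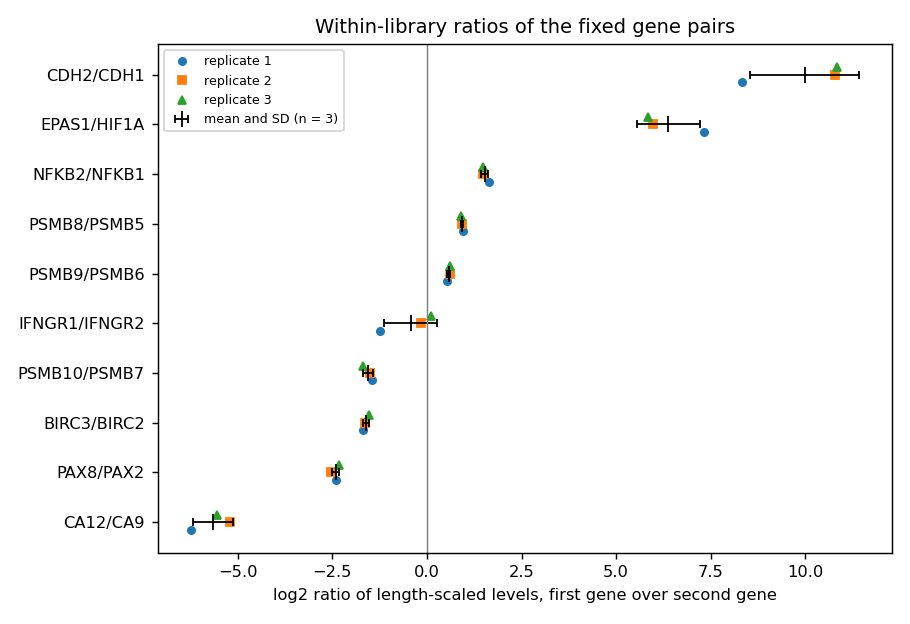
Log2 ratio of length-scaled levels within each library (horizontal axis) for 10 of the 14 measured gene pairs, first gene over second gene. Circles, squares and triangles are replicates 1, 2 and 3, and black bars are mean ± SD (n = 3); IFNGR1/IFNGR2 is the pair whose libraries differ in sign.

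No excess of variation between libraries was detected for the cytokine-response lists against other genes of the same expression. The median coefficient of variation was 14% for IFN-gamma signalling, 13.6% for interferon-stimulated effectors, 11.7% for MHC class I presentation and 17.4% for the TNF pathway. Matched random lists gave 15.3%, 15.7%, 15% and 15.5%. With GC correction the 4 lists stood at 7.59%, 7.97%, 5.44% and 5.48% against 7.87%, 8.03%, 6.68% and 7.32%, so the TNF pathway moved from above to below its random lists. Of the 16 lists with enough detected members, 0 passed the random-list test after adjustment. The HIF list, at 10.6% against 15.5%, was the only list with an unadjusted p under 0.05, at percentile 1.49 of its random lists (adjusted p = 0.48). With GC correction it stood at 10.9% against 7.91%, above most of its random lists (percentile 92.2, adjusted p = 0.87). Of 48 list and library combinations, 0 passed the random-list test of deviation and 0 had an unadjusted p under 0.05. With GC correction 0 of 48 passed and 2 had an unadjusted p under 0.05, the lower being IFN-gamma signalling in replicate 2, at percentile 99.8 of its random lists (adjusted p = 0.19). At the spread of these libraries such tests miss small shifts: of 10 simulated lists raised 1.2-fold in replicate 1, 2 were found by deviation and 0 by coefficient of variation.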

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

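The alternatives that leave out covered genes, use the exon length outside other spans, correct for GC content or take the authors' scaling were chosen after seeing the data. The number of list genes detected (234) stayed between 192 at 10 CPM and 261 at 0.1 CPM, the lists past the level test (9) between 9 and 12, and the pairs past the spread (13) between 12 and 14. No list passed the tests of spread or of deviation under any alternative run, though simulations show that these tests miss small shifts. IFN-gamma minus TNF, not past the test, ran from -1.17 without length scaling to 0.035 without covered genes. The class I minus class II difference (9.62) stayed between 7.0 with a pseudocount of 1 and 10.5 without length scaling. The coefficient of variation moved: against 0.281, leaving out a replicate gave 0.0731 (without replicate 1) to 0.373 (without replicate 2), and GC correction gave 0.184. Of what remained after GC content, a length trend stayed open and fewer cycling cells were argued against, as weighed with the other observations. For the other results, leaving out a replicate gave 235 to 238 list genes, 9 lists, 12 to 13 pairs, 9.58 to 9.70 for class I minus class II and -0.72 to -0.64 for IFN-gamma minus TNF. Of the single lists and pairs, 2 reversed. Against detected genes only, the MHC class II list lay 3.86 above random lists (adjusted p = 0.017), since only its 3 detected members remained. PAX8/PAX2 turned to 2.13 with the exon length outside other spans, which removes 95.7% of the PAX8 length. In 6 list and alternative combinations over 3 lists (haematopoietic, antigens, chemokines) a level newly passed the test and in 1 (cell death) it no longer did; against detected genes the fibroblast list had no member left to test. IFNGR1/IFNGR2 passed the spread under GC correction, and 13 list detection counts moved by over 1.5 times, in the class II, chemokine, checkpoint, renal, haematopoietic, endothelial and fibroblast lists. EPAS1/HIF1A fell from 6.38 to 2.70 with the exon length outside other spans. Changes of library scaling cancel within a pair ratio and test nothing there. No paired analysis was possible because there is 1 group. Depth does not limit the levels of abundant genes, while ratios with CDH1 or HIF1A rest on fewer than 100 reads a library.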

Other observations

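Several gene groups outside the fixed lists, chosen after the data were examined but before their own levels were seen, describe these cells further. Of 10 receptor tyrosine kinases 7 were detected, with AXL at 141 ± 40.8 RPKM (SD, n = 3), EPHA2 at 39.4 ± 4.92 and EGFR at 33.9 ± 3.42 RPKM, while RET and KIT were listed at 0 reads in each library. All 5 chromatin genes often mutated in clear cell carcinoma were detected, from BAP1 at 19.7 ± 3.04 to PBRM1 at 0.498 ± 0.215 RPKM; PBRM1 has 52.1% of its exons inside other spans. SETD2 had 688, 1658 and 2162 reads in replicates 1, 2 and 3. Of 7 genes that control iron and lipid peroxidation all were detected. The covered gene SLC7A11 passed narrowly, with 28, 80 and 86 reads and 1.03 CPM in replicate 1 against the limit of 1. FTL stood at 1504 ± 315, FTH1 at 325 ± 27.9 and GPX4, which reduces lipid peroxides, at 145.5 ± 29.6 RPKM. FTH1 has 70.99% of its exons inside other spans. Of 8 lipid and one-carbon genes 5 were detected. ACLY and FASN stood at 102 ± 17.9 and 31.1 ± 8.45 RPKM. FBP1, with 25.3% of its exons inside other spans, was listed at 0 reads in each library, as were the covered genes NNMT and HILPDA. Of 4 genes for receptors of type I and III interferons 2 were detected; IFNAR1 stood at 7.88 ± 1.57 and IFNLR1 at 1.14 ± 0.163 RPKM, and IFNAR2, a covered gene, had 6, 2 and 2 reads.

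Of the most abundant genes annotated as long noncoding RNAs, MALAT1, with a GC content of 39.6%, stood at 92.9, 453 and 552 CPM in replicates 1, 2 and 3. NEAT1, with a GC content of 45.5%, stood at 37.9, 152 and 176 CPM. FGD5-AS1 stood at 105, 99.9 and 107 CPM. CH507-528H12.1 was listed at 6946, 7047 and 2534 CPM and CH507-513H4.1 at 5309, 4279 and 4597 CPM; their equal exon length (2498) and GC content leave the split of reads between them uncertain.

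In the weighing that follows, the tests on genes listed at 0 and on MHC class II were chosen after the result was seen, and those on replicate 1 were set before their results were seen. The design has 1 group, so no biological explanation for a difference between conditions was tested.

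Ribosomal protein and interferon-response genes, among them RPL15, IRF1 and TAP1, were listed at 0 reads in each library. Silence of the genes is argued against as a general account, since 90.0% of 10 covered ribosomal protein genes were below 1 CPM against 2.86% of 70 others, though the true level of any single covered gene stays unknown. Counting over exons alone is argued against, since 0 of 666 genes inside a span with no shared exon were detected (0%), and so is strand-specific counting, since 0.211% of 947 genes covered only from the opposite strand were. A candidate explanation is counting over whole gene spans on both strands with reads in 2 genes discarded, since 1.91% of 2150 wholly covered genes were detected against 52.4% of 9483 without overlap. It leaves open SDHA and PDCD1LG2, at 0 reads, and EGLN1, at 1, 0 and 0, which have no overlap in GENCODE 29, and the authors' own annotation was not used here.

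Replicate 1 had far fewer reads than the others in 1245 of 9095 genes. Fewer cycling cells are argued against, since proliferation genes had a median log2 deviation of 0.068 after GC bin medians were removed, inside the range of random lists (-0.196 to 0.148). GC bias in preparing replicate 1 may account for much of it, with a Spearman rho across genes of 0.793, but replicate 3 over replicate 2 also trended with GC (rho -0.47, limit 0.3 in size), so the test set beforehand was not met in full. After GC bin medians were removed, 379 genes stayed below 50% and the SD of the deviation fell from 0.78 to 0.471, against 0.167 between replicates 3 and 2. Transcript length or RNA fragmentation stays open, since its residual rho of -0.173 lay between the bounds set for and against it.

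MHC class II genes were near 0 beside CD74 and CIITA. Of the class II genes with a mean below 1 CPM, 6, HLA-DRA among them, had under 20% of their exons covered. For these 6 genes, loss of most reads to spans in the annotation used here is argued against. Loss to spans found only in the authors' annotation stays open, since 2268 of the deposited genes had no match here. SDHA was listed at 0 reads in each library with 0% of its exons covered. Bias of 1 library is argued against, since the median over the 9 class II list genes under 20% covered was at most 0.368 CPM in any library. No biological explanation was tested. The 47% of CIITA exons inside other spans and the absence of an untreated library from this work leave its own level and any induction open.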
